A study of Arabidopsis thaliana with 8 samples.

How the data were processed

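RNA from whole dark-grown *Arabidopsis thaliana* seedlings was measured on 8 Affymetrix ATH1 arrays, 2 biological replicates in each of 4 groups: control, heat, anoxia, and heat then anoxia. The deposited values are intensity values on a linear scale, made per the labels with GCRMA, a method that models background from probe sequence; its version was not given in the sources used here. The median intensity per array was 36.8 to 53.2, and 58.1% to 60.6% of probe sets reached the filter in each array.

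The log2 of each deposited intensity was taken with no further normalization. Of 22810 probe sets, 64 array controls were set aside, and 14535 of the remaining 22746 had a log2 value of at least 4 in at least 2 of the 8 arrays. Group means were fitted with limma 3.58.1 in R 4.3.3 with empirical Bayes moderation, on 4 residual degrees of freedom, and the figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 6 comparisons were heat, anoxia and heat then anoxia each against control, heat then anoxia against anoxia and against heat, and the interaction. A probe set was called higher or lower at a Benjamini-Hochberg adjusted p below 0.05, taken within each comparison, and at least a 2-fold change.

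Gene names came from the platform annotation and a RefSeq name table, which list 1 gene for 13513 probe sets, several for 503 and none for 8730. Genes were named from the 8 highest and 8 lowest log2 fold changes of each comparison among called probe sets that match 1 gene and whose arrays do not overlap between groups (the last condition was not used for the interaction). They were also named from the 4 members of each fixed list with the largest absolute change, not all of which are printed. A further source was 16 chosen genes, of which only PDC2 was matched to a named probe set. Other names are said to have been chosen after their values were seen. A gene with several probe sets was represented in lists by its brightest one.

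Gene lists fixed before the data were examined held 274 loci, of which 61 were measured. Here a measured gene is one matched by the name tables to a probe set that passed the filter. All 61 loci that were named passed it, so the other loci of these lists are missing for want of a name. The heat shock transcription factor, sugar starvation and seed storage lists had 0 measured genes. A planned list of cytosolic ribosomal proteins was not run, since the name tables give no descriptions. Lists of class III peroxidases, calmodulin-like proteins, root hair-specific genes, root endodermis genes, and mitochondrial- and plastid-encoded genes were added after the data were seen. Lists with at least 3 measured genes, 13 in all, were tested with camera in limma at a preset correlation of 0.01, and the 78 tests were adjusted together. No list call held with an estimated correlation. The alternative fry changed the call of none of the 18 results for small heat shock proteins, larger chaperones and core hypoxia genes. The comparisons, thresholds and naming rule were fixed at the same time.

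The procedure was tested on simulated data in the comparison of heat with control, with 50 probe sets changed at each size. It recovered 0%, 64%, 88% and 100% of changes of 1, 2, 3 and 4 on the log2 scale with 5 false calls, and it made 0 calls in an unchanged comparison. The overlap of heat and anoxia calls was set against 100 simulations of unchanged groups sharing the controls. Alternatives were no filter, a stricter filter at log2 6, an intensity trend with a robust prior, only the 2 groups compared, quantile normalization, median centring, a block for replicate number, no fold threshold, adjusted p below 0.01, no cross-hybridising probe sets, each array left out in turn, and for lists an estimated correlation, fry and the mean of all probe sets of a gene. Leaving out the 2 arrays with a high 25S ribosomal RNA signal was added after the data were seen. When 1 array was left out, the lone array of its group was assumed to vary like the other groups.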

Results

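Transcript levels were measured in whole *Arabidopsis thaliana* seedlings of the ecotype Columbia 0 that had been grown in the dark for 4 days in liquid medium with 30 mM sucrose. Per the labels, seedlings were left at 23 °C as controls, were heated to 38 °C for 90 minutes, were kept without oxygen (anoxia) for 6 hours at 23 °C, or were heated for 90 minutes and then kept without oxygen for 6 hours. Each of the 4 groups was represented by 2 biological replicates, and each replicate by 1 Affymetrix ATH1 array, so that the number of arrays limits the precision of every value. Of 22746 probe sets other than array controls, 14535 passed the filter on dim signals. Replicates correlated at 0.965 to 0.979 across probe sets, and the share of probe sets that differed more than 2-fold between replicates ran from 5.53% in heat to 10.8% in anoxia. On the first principal component, which held 63.6% of the variance, the heated groups (63.9 to 93.1) lay apart from the control and anoxia arrays (-109 to -42.7). The platform table names a gene for 7823 of the 14535 probe sets, so most well-known genes of either stress, among them 15 of 16 chosen in advance, were unnamed here and are not reported.

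The comparison of heat with control asked what 90 minutes at 38 °C did to the seedlings. Small heat shock proteins, which bind unfolding proteins, were among the strongest rises. AT1G53540, a class I member, went from a mean of 2.23 ± 0.09 (SD, n = 2) on the log2 intensity scale in controls to 14.9 ± 0.12 in heat, a log2 fold change of 12.63 ± 0.28 (SE; limma adjusted p = 2.33e-07). AT1G52560 rose by 12.25, the mitochondrial AT5G51440 by 9.75 and the class III member AT1G54050 by 8.60. Of 9 measured members of the list 7 rose (7 adjusted over the list alone), and the other 2, AT4G21870 and AT5G47600 (named after their values were seen), stood at 0.03 and -0.56. Of 9 measured HSP70, HSP90 and HSP100 chaperones and their co-chaperones 8 rose (8 adjusted over the list alone), led by Hop3, which links HSP70 to HSP90, at 9.52, the J-domain protein AT2G20560 at 8.48, the FK506-binding protein AT5G48570 at 8.30 and the HSP70-binding protein Fes1A at 7.44. The medians of these lists were 8.13 and 7.24 (camera adjusted p = 3.77e-09 and 4.06e-10), with adjusted p = 0.116 and 0.146 with an estimated correlation.

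Other genes among the 8 strongest rises in heat were AT1G71000, which encodes a J-domain chaperone (11.47), AT5G53680 (9.85), AT1G44414 (9.80) and AT3G07150 (9.74). The strongest falls included AT5G57760 (-6.18), the pectin methylesterase gene ATPMEPCRB (-5.36), AT5G54370 (-5.13), the gene PR-1-LIKE (-4.90), the subtilase gene SBT4.12 (-4.81), AT1G21050 (-4.79), AT3G49210 (-4.74) and AT1G56020 (-4.63), with adjusted p of 0.00187 or lower for each. All 3 measured genes of cell wall loosening fell (3 adjusted over the list alone), namely the expansin gene EXPA8 (-2.78) and the xyloglucan-modifying enzymes XTH19 (-2.08) and XTH18 (-1.47). That list had camera adjusted p = 0.0306 and adjusted p = 0.361 with an estimated correlation. The root hair expansin genes EXPA7 and EXPA18 fell as well (-2.99 and -2.92), EXPA7 by -1.93 without control replicate 1. Of 22 measured core hypoxia genes 4 rose and 6 fell (4 and 7 adjusted over the list alone), with a median of -0.41, a mean of -0.19 and an upward camera direction at adjusted p = 0.902. The median was -1.11 without control replicate 1 and 0.03 without control replicate 2. Between the controls, 10 of the 22 genes were more than 2-fold higher in replicate 2. The risers were AT3G10020 (6.82), the universal stress protein gene AT3G03270 (4.08), AT3G23170 (3.39) and AT4G17670 (1.36, named after its value was seen), and AT5G66985 fell furthest (-3.40). PDC2, a pyruvate decarboxylase of ethanol fermentation, rose by 2.00 ± 0.26, while the other 2 measured genes of its list, AT4G17260 (lactate dehydrogenase) and PPDK, stood at -0.40 and 0.22. The zinc finger gene STZ rose by 5.12 ± 1.12, with its 2 control arrays far apart at 2.94 and 7.29. Its log2 fold change was 2.95 without control replicate 1 and 7.29 without control replicate 2. The endoplasmic reticulum co-chaperone gene ATERDJ3B rose by 1.60.

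Across all 14535 probe sets 1524 were higher and 2605 lower in heat than in control (limma, Benjamini-Hochberg adjusted p below 0.05 and at least 2-fold). The median log2 fold change of all probe sets was -0.22, against which these changes should be read. The 4 measured reference genes, including the ubiquitin-conjugating enzyme PEX4 and the tubulin TUB6, were not called by limma in any of the 6 comparisons, although 1 had an unadjusted p below 0.05 here and 1 in heat then anoxia against anoxia. A signal below log2 4, such as that of AT1G53540 in controls, lies near the array's background, so the size of a fold against it depends on the background model.

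**Figure D1:**
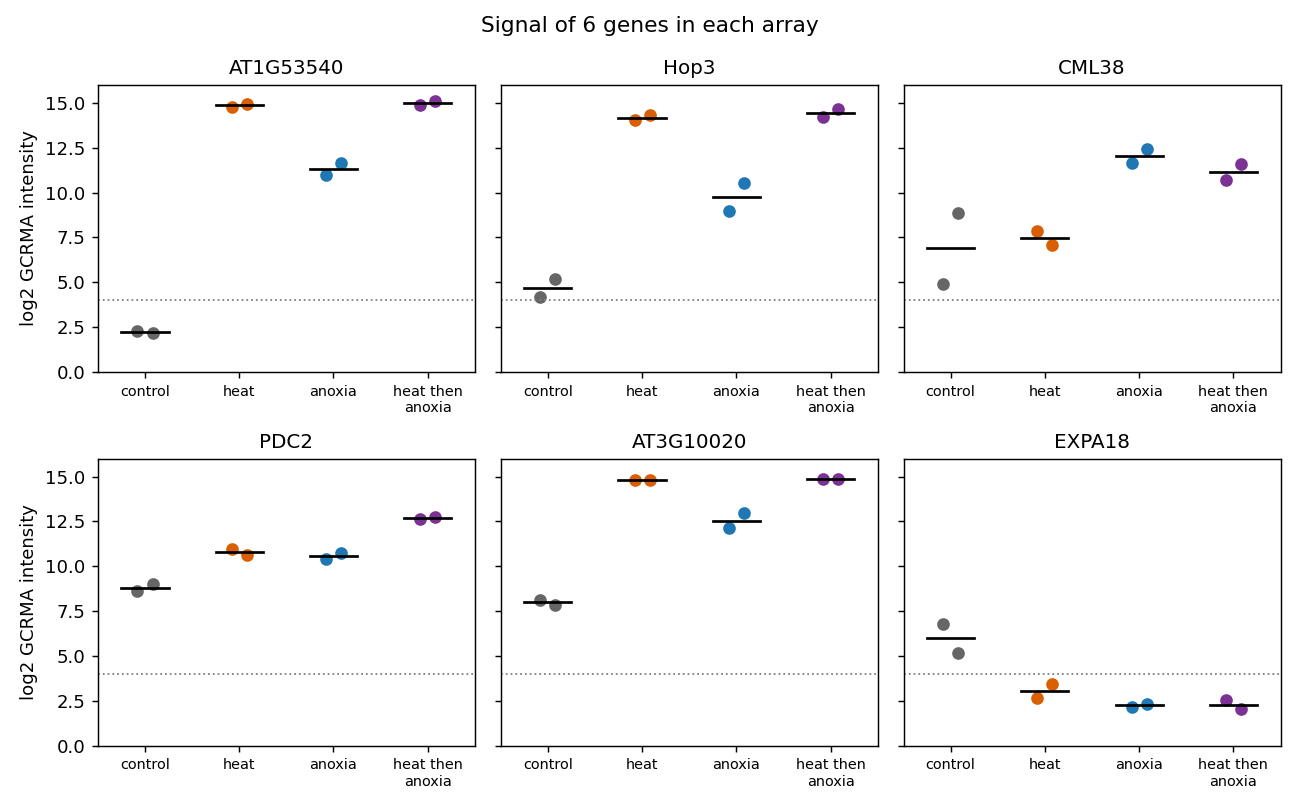
Log2 GCRMA intensity of 6 genes in each array (dots, 2 per group) with the group mean (bar); the dotted line is the filter at log2 4. AT1G53540 and Hop3 stand near 15 and 14 in both heated groups and at 11.3 and 9.77 in anoxia, and PDC2 is highest after heat then anoxia at 12.7.

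The comparison of anoxia with control asked what 6 hours without oxygen did at 23 °C. Small heat shock protein genes were again among the strongest rises, with AT1G53540 at 9.08 ± 0.28 (SE; limma adjusted p = 2.92e-06), AT1G52560 at 8.67, AT5G51440 at 7.09 and AT1G54050 at 6.36. Of 9 measured members 7 rose (7 adjusted over the list alone) with a list median of 5.62, and of 9 larger chaperones 5 rose (5 adjusted over the list alone) with a median of 2.96, led by Hop3 at 5.11 and AT5G48570 at 4.37. Camera gave adjusted p = 4.36e-12 and 3.44e-06 for these lists, and adjusted p = 0.116 and 0.226 with an estimated correlation. AT2G41730 rose by 8.11, the J-domain chaperone AT1G71000 by 6.95, the dioxygenase-like gene AT5G43450 by 6.92, AT1G76600 by 6.75 and AT5G14730 by 6.74.

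Of 22 measured core hypoxia genes 12 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 1.80 (camera adjusted p = 3.18e-11, and adjusted p = 0.154 with an estimated correlation). CML38, a calmodulin-like protein, rose by 5.14 ± 1.09 (adjusted p = 0.0229), AT5G10040 by 4.86, AT3G10020 by 4.55 and AT3G03270 by 2.64. The controls differed here: 10 of the 22 genes were more than 2-fold higher in control replicate 2 than in replicate 1, against 4.11% of all probe sets, and CML38 stood at 8.89 and 4.89 in them and AT5G10040 at 5.99 and 2.66. Without control replicates 1 and 2 the log2 fold changes were 3.15 and 7.14 for CML38 and 3.19 and 6.53 for AT5G10040. Without anoxia replicate 1 or replicate 2, CML38 had adjusted p = 0.0629 and 0.118, and AT5G10040 had 0.0610 and 0.0517. PDC2 rose by 1.78 ± 0.26, and AT4G17260 (1.36, adjusted p = 0.0543) and PPDK (1.19) did not pass over all probe sets, while all 3 genes passed when adjusted over the list alone. AT4G17260 passed over all probe sets without either heat array (adjusted p = 0.0207), and camera gave adjusted p = 0.00553 for the fermentation list and adjusted p = 0.232 with an estimated correlation.

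STZ, BZIP60 and GSTU25, a glutathione transferase gene, stood at 4.89, 1.49 and 2.15. STZ stood at 2.72 without control replicate 1, and it had adjusted p = 0.0306, which was 0.0931 and 0.132 without anoxia replicates 1 and 2, 0.0547 without either heat array and 0.0513 without either heat then anoxia array. BZIP60 had adjusted p = 0.0249, which was 0.129 and 0.0582 without control replicates 1 and 2 and 0.117 without anoxia replicate 2. GSTU25 was not called in limma (adjusted p = 0.0858), and it stood at 1.02 without control replicate 1 and at 3.28 without control replicate 2. The list of antioxidant and reactive oxygen response genes had 1 of 3 genes called, the zinc finger gene STZ (2 adjusted over the list alone). Its camera adjusted p was 0.0426, with adjusted p = 0.479 with an estimated correlation. That list had 0.0506 without heat replicate 2 and 0.0860 and 0.0947 without anoxia replicates 1 and 2. The unfolded protein response list had a median of -0.70, a mean of 0.02 and a downward camera direction at adjusted p = 0.686.

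Falls under anoxia were led by class III peroxidases, secreted enzymes that act on the cell wall. AT1G30870 (-4.85), AT1G34510 (-4.75) and AT4G26010 (-4.50) fell furthest, next to AT2G25250 (-4.06), the glycosyltransferase gene AT1G08280 (-3.97), AT2G14460 (-3.82), EXPA18 (-3.73) and AT1G49975 (-3.54). AT1G49975 was not called without control replicate 1 (adjusted p = 0.0673) or without anoxia replicate 2 (0.0677). The other root hair expansin, EXPA7, stood at -3.22 with adjusted p = 0.0112, and at 0.0510 and 0.0577 without anoxia replicate 1 or 2. The cell wall list, with 0 of 3 members called (2 fell adjusted over the list alone), had camera adjusted p = 0.301, and XTH19 and EXPA8 passed without anoxia replicate 2 (-1.70 and -1.83). In all, 574 probe sets were higher and 860 lower, and the median of all was -0.01. Without anoxia replicate 2 the higher count was 358, and the lower count was 502 without control replicate 1 and 454 without control replicate 2. It was 524 when the fit held only the 2 groups compared.

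Heat and anoxia calls overlapped in both directions. Probe sets higher in both numbered 313, which is 54.5% of those higher in anoxia, against 60.2 for independent lists of these sizes, and those lower in both numbered 641 (74.5%), against 154. Opposite calls numbered 64, against 193. Shared rises held AT1G53540, AT1G52560, Hop3, AT3G10020, AT3G03270 and PDC2, and shared falls held AT1G30870, AT1G34510 and EXPA18. Unchanged groups simulated against the same controls gave at most 0 shared calls in 100 simulations. Such groups yield almost no calls, so this gives no expected overlap for lists of these sizes. The simulated correlation of 0.499 across probe sets, where 0.569 was observed, follows from the common controls. The simulated covariance was 0.0620 where 0.817 was observed, so noise in the controls, as simulated, gave a small part of the shared fold changes. The 2 controls cannot be split further, so part of the excess may come from sharing them, and probe sets are not independent replicates. The count lower in both was 402 without control replicate 1, 355 without control replicate 2 and 418 when each fit held only the 2 groups compared.

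Seedlings that were heated and then kept without oxygen were compared with controls to describe the combined treatment. AT1G53540 was higher by 12.76 ± 0.28 (SE; limma adjusted p = 2.14e-07), AT1G52560 by 12.33, AT1G71000 by 11.003, AT5G53680 by 10.56, AT5G51440 by 9.81, Hop3 by 9.77, AT3G07150 by 9.69 and the GTP-binding protein gene AT1G72660 by 9.65. Of 9 small heat shock proteins 7 rose (7 adjusted over the list alone, median 8.17, camera adjusted p = 5.63e-08), and of 9 larger chaperones 8 rose (8 adjusted over the list alone, median 7.25, camera adjusted p = 3.09e-08), with adjusted p = 0.116 and 0.171 with an estimated correlation. The fermentation genes PDC2 and AT4G17260 rose by 3.90 and 3.06, and PPDK stood at 0.83, or 1.39 and called without control replicate 2 (2 of 3 adjusted over the list alone; camera adjusted p = 0.0136, and adjusted p = 0.271 with an estimated correlation). Of 22 core hypoxia genes 7 rose and 3 fell (7 and 3 adjusted over the list alone) with a median of 0.92, and camera gave adjusted p = 0.00148, with adjusted p = 0.407 with an estimated correlation. The median was 0.46 without control replicate 1 (adjusted p = 0.0442) and 1.57 without control replicate 2. CML38 stood at 4.27 with adjusted p = 0.0139, which was 0.0724 without heat then anoxia replicate 2, and at 2.27 without control replicate 1. In the unfolded protein response, BZIP60, a transcription factor of that response, rose by 2.07 and ATERDJ3B by 1.99, while the calreticulin gene CRT1b stood at 0.93 below the 2-fold limit; the list of 3 had camera adjusted p = 0.0166 and adjusted p = 0.232 with an estimated correlation. STZ rose by 6.21 ± 1.12 (4.04 without control replicate 1). Its list of 3 antioxidant and reactive oxygen response genes had camera adjusted p = 0.0955. The list median was 2.47, or 1.34 without control replicate 1 and 3.60 without control replicate 2. GSTU25 of that list stood at 2.47 with adjusted p = 0.0166, which was 0.0505 (at 1.34) without control replicate 1 and 0.0827 without heat then anoxia replicate 2.

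Falls in the combined treatment were led by AT5G57760 (-6.85), the peroxidase gene AT2G18980 (-6.10), the endoglucanase gene GH9C2 (-5.68), the pectate lyase-like gene AT4G24780 (-5.63), the aspartyl protease gene AT3G61820 (-5.58), AT2G41950 (-5.53), AT1G15260 (-5.51) and AT4G07820 (-5.44), with adjusted p of 0.000760 or lower for each. EXPA8 (-2.34), XTH19 (-1.68) and XTH18 (-1.25) fell (3 adjusted over the list alone), although camera gave adjusted p = 0.0970 for their list. EXPA18 (-3.69) and EXPA7 (-3.11, or -2.05 without control replicate 1) fell too. PORB, a protochlorophyllide reductase and the only measured gene of the photosynthesis list, fell by 1.90 ± 0.23 on the log2 scale. PRL, a subunit of the DNA replication helicase and the only measured cell cycle gene, stood at -1.81 with adjusted p = 0.0282, which was 0.0802 without control replicate 1, 0.112 without control replicate 2 and 0.153 without heat then anoxia replicate 2. EIN3, the only measured ethylene signalling gene, was not called in any comparison and stood at -0.24 here. In all 2205 probe sets were higher and 3686 lower, at a median of -0.33 over all probe sets.

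The comparison of heat then anoxia with anoxia alone asked what the preceding heat changed in seedlings without oxygen. AT1G10260 was higher by 8.42 ± 0.30 (SE; limma adjusted p = 1.17e-05), the thaumatin-like gene AT4G36010 by 7.82, the calmodulin-like gene AT1G21550 by 7.26, AT5G62730 by 6.62, AT1G27285 by 6.47, AT3G62780 by 6.35, AT4G33660 by 6.23 and the deaminase gene AT3G48540 by 6.04. Small heat shock proteins were higher by a median of 2.55 (7 of 9, and 7 adjusted over the list alone), and larger chaperones by a median of 4.00 (8 of 9, and 8 adjusted over the list alone), among them Hop3 at 4.66, Fes1A at 4.65 and Hsp70-2 at 4.43. Camera gave adjusted p = 1.29e-05 and 6.37e-08, with adjusted p = 0.135 and 0.175 with an estimated correlation. PDC2 was higher by 2.12 ± 0.26 and AT4G17260 by 1.71, the latter at adjusted p = 0.0567 without heat then anoxia replicate 2, and their list had camera adjusted p = 0.0970. ATERDJ3B and CRT1b were higher by 2.73 and 1.63 (2 of 3 adjusted over the list alone; camera adjusted p = 0.0112, and adjusted p = 0.226 with an estimated correlation).

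Core hypoxia genes moved both ways with the preceding heat, 4 higher and 7 lower of 22 (4 and 7 adjusted over the list alone), with a median of -0.86 (camera adjusted p = 0.645). AT5G66985 was lower by -5.16 ± 0.54 and AT3G10020 higher by 2.32. AT5G10040 stood at -4.04 with adjusted p = 0.0103, which was 0.0594 without anoxia replicate 1, and AT1G74940 at -2.67 with 0.0122, which was 0.0610 without anoxia replicate 2, and with -1.69 without heat then anoxia replicate 1. Other strong falls were AT5G57760 (-5.08), AT3G22210 (-4.69), AT2G03420 (-4.61), the anthocyanin malonyltransferase gene AT5MAT (-4.48), the glucosyltransferase gene AT1G01390 (-4.40), AT1G15260 (-4.32) and AT5G43520 (-4.16), with adjusted p of 0.000298 or lower. XTH18 was lower by -1.52 while EXPA8 and XTH19 were not called, except EXPA8 without anoxia replicate 1 at -1.66 (2 lower adjusted over the list alone; camera adjusted p = 0.242). PORB was lower by -1.51. PRL stood at -1.70 with adjusted p = 0.0452 and was not called without either control array (0.0669), anoxia replicate 1 (-1.03, 0.229), heat then anoxia replicate 1 (0.0576) or heat then anoxia replicate 2 (0.216). In all 1857 probe sets were higher and 2493 lower, at a median of -0.31. This comparison shares no array with that of heat and control: 1191 of the 1524 probe sets higher in heat (78.1%) were also higher here, against 195 for independent lists, and 1098 of the 2605 lower in heat (42.1%) were also lower, against 447. The correlation of the fold changes across probe sets was 0.715.

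**Figure D2:**
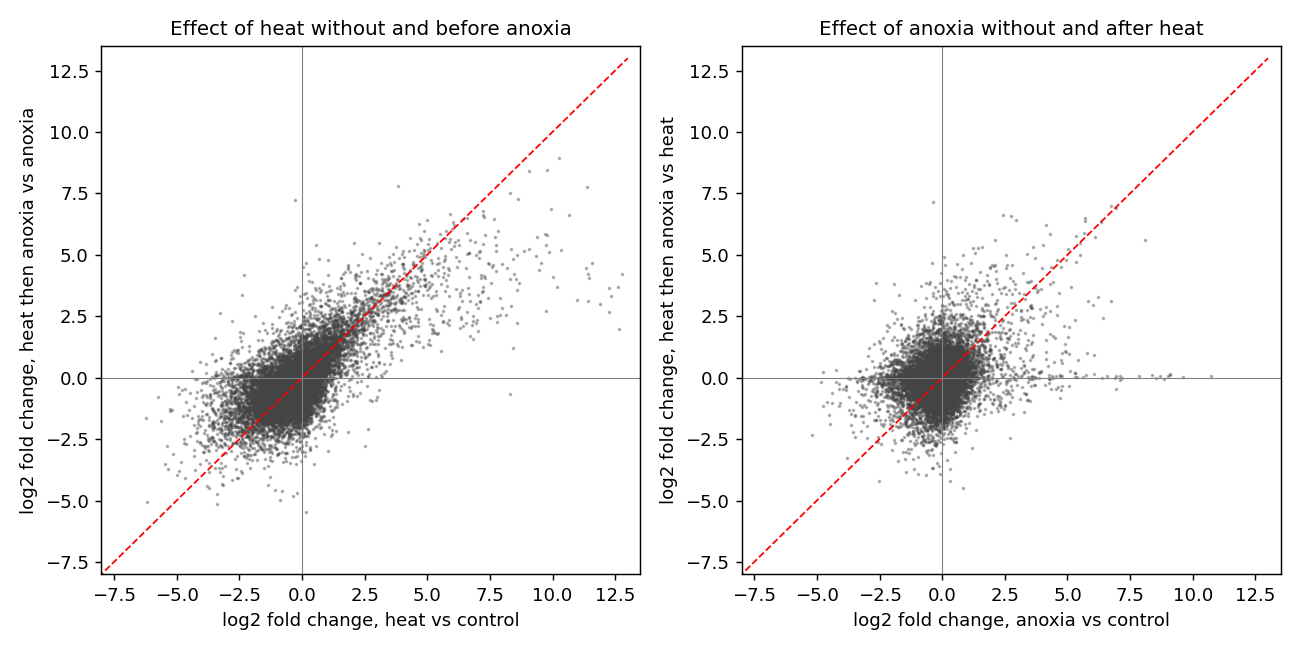
Log2 fold change of each of the 14535 probe sets (dots) for heat without anoxia against heat before anoxia (left) and for anoxia without heat against anoxia after heat (right), with the line of equal change dashed. The correlation across probe sets is 0.715 on the left and 0.306 on the right.

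The comparison of heat then anoxia with heat alone asked what anoxia did after heat; the time between heat and harvest in the heat group is not given in the sources used here, so the groups may also differ in time after heat. AT5G14730 was higher by 6.999 ± 0.54 (SE; limma adjusted p = 0.000745), AT5G43450 by 6.92, AT1G70420 by 6.57, the glutaredoxin gene GRX480 by 6.49, the glutamine amidotransferase-like gene GAT1_2.1 by 5.72, the dioxygenase gene AT5G05600 by 5.62, AT2G41730 by 5.62 and AT2G32020 by 5.48. Of 22 core hypoxia genes 9 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 1.302 (camera adjusted p = 8.81e-07, and adjusted p = 0.232 with an estimated correlation). The fall was that of AT5G44730 (-1.04), named after its value was seen. The 4 largest changes in the list were not called in every setting. AT3G10040, a trihelix transcription factor gene, stood at 3.34 and AT4G10270 at 2.97; without heat replicate 2, heat then anoxia replicate 1 and heat then anoxia replicate 2 they had adjusted p of 0.0977, 0.0680 and 0.114 (at 2.44 to 3.51), and of 0.0964, 0.0877 and 0.121 (at 2.02 and above). AT4G39675 stood at 2.83, with 0.0545, 0.0604 and 0.0515 (at 2.89, 2.77 and 2.52) without heat replicate 1, heat replicate 2 and heat then anoxia replicate 1. CML38 stood at 3.69 with adjusted p = 0.0716 and passed without either control array (0.00862). AT4G17260 rose by 3.46 ± 0.36 and PDC2 by 1.90 ± 0.26 (2 of 3 adjusted over the list alone; camera adjusted p = 0.00290, and adjusted p = 0.226 with an estimated correlation). Of 9 small heat shock proteins and 9 larger chaperones 0 were called in limma (0 adjusted over each list alone, and 0 at an unadjusted p below 0.05), with medians of 0.06 and 0.07, AT1G53540 at 0.14 ± 0.28 and Hop3 at 0.25 ± 0.53. AT1G53540 and Hop3 stood at 14.86 and 14.18 in heat, near the top of the array's range, where a further rise may not show.

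The strongest falls after heat were those of COR15B, a cold-regulated plastid protein (-4.48), AT2G41950 (-4.22), AT3G22210 (-4.20), the vacuolar processing enzyme gene DELTA-VPE (-3.98), AT1G56050 (-3.93), AT2G03420 (-3.92), the ethylene-insensitive3-like gene AT5G10120 (-3.83) and AT5G52780 (-3.73). Of these 8, 4 lost their call when 1 array was left out. AT2G41950 had adjusted p of 0.0808, 0.0664, 0.0653 and 0.0692 without heat replicate 1, heat replicate 2, heat then anoxia replicate 1 and heat then anoxia replicate 2, and AT1G56050 had 0.0859, 0.0619, 0.0540 and 0.0884. DELTA-VPE had 0.0633 without heat replicate 2 and 0.0672 without heat then anoxia replicate 2, and AT5G52780 had 0.0657 without heat replicate 1 and 0.0671 without heat then anoxia replicate 2. PORB stood at -1.35 with adjusted p = 0.0135, which was 0.0739, 0.0742 and 0.0948 without heat replicate 1, heat replicate 2 and heat then anoxia replicate 2. In all 746 probe sets were higher and 678 lower, at a median of -0.05. The counts were lower with any 1 of the 4 arrays left out: without heat replicate 1, heat replicate 2, heat then anoxia replicate 1 and heat then anoxia replicate 2 the higher counts were 348, 288, 466 and 212, and the lower counts 110, 144, 235 and 160. With no filter on dim probe sets they were 423 and 338. Of the 574 probe sets higher in anoxia against control, a comparison with no array in common, 183 (31.9%) were also higher here, against 29.5 for independent lists, and 75 of the 860 lower (8.72%) were also lower, against 40.1. Of the 574 and the 860, 313 and 641 were already called in the same direction in heat against control. For those near background or near the top of the range in heat, a further change may not be measurable here. The count of 183 was 114, 121, 117 and 88 without heat replicate 1, heat replicate 2, anoxia replicate 2 and heat then anoxia replicate 2, and the count of 75 was 38 and 46 without control replicates 1 and 2, 21 and 26 without heat replicates 1 and 2, 153 and 45 without anoxia replicates 1 and 2, and 34 and 28 without heat then anoxia replicates 1 and 2.

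The interaction of heat and anoxia tested whether the combined treatment departed from the sum of the single effects on the log2 scale; the unstated time from heat to harvest enters it as well. Chaperone genes had the most negative values, with AT1G53540 at -8.95 ± 0.39 (SE; limma adjusted p = 4.34e-05), AT1G52560 at -8.60, AT1G71000 at -7.42, AT5G51440 at -7.03, AT1G54050 at -6.38, ATHSP22.0 of the endoplasmic reticulum at -5.58 and Hop3 at -4.86. Of 9 small heat shock proteins 7 had a negative interaction (7 adjusted over the list alone, camera adjusted p = 3.24e-10) and of 9 larger chaperones 5 (5 adjusted over the list alone, camera adjusted p = 0.000105), with adjusted p = 0.116 and 0.271 with an estimated correlation. AT1G53540 stood at 14.86, 11.31 and 14.99 in heat, anoxia and heat then anoxia, and all 7 genes just named lay above log2 13 in heat and in heat then anoxia, near the top of the array's range. A further rise may not be measurable at such levels, so these values and their limma p-values are no evidence of a departure from the sum. The same limit applies to the list results where they rest on such genes. AT3G10020 and AT3G03270, given below, also lay above log2 13 in heat and in heat then anoxia. Positive interactions were led by AT3G06070 (6.48), AT1G69760 (5.89), the glucanase-like gene AT3G04010 (5.75), the peroxidase gene AT1G30870 (4.66), AT3G55840 (4.48), AT1G67340 (4.34), AT1G21050 (4.30) and the pectate lyase-like gene AT3G07010 (4.14). AT1G30870 lay below log2 3 in all 6 treated arrays, near background. A further fall may not be measurable there, so its value is no evidence of a departure from the sum. AT3G55840 stood between 2.52 and 2.63 in the other 3 groups and at 7.15 after heat then anoxia. PDC2 had an interaction of 0.12 ± 0.36 (adjusted p = 0.877), and AT4G17260 of 2.11 (adjusted p = 0.0537, or 0.0236 without heat replicate 1). Core hypoxia genes had 2 negative calls of 22 (2 adjusted over the list alone), AT3G10020 (-4.50) and AT3G03270 (-2.25), and camera adjusted p = 0.0999 for the list, which was 0.000279 without control replicate 2.

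In all 542 probe sets had a positive and 356 a negative interaction. Of the 313 probe sets higher in both single treatments 180 had a negative interaction, and of the 641 lower in both 245 had a positive one, 97 of them with means below log2 4 in all 3 treated groups, where this limit applies as well. The positive and negative counts were 292 and 235 without control replicate 1, 257 and 179 without control replicate 2, 281 and 162 without heat replicate 1 and 198 and 153 without heat replicate 2. They were 250 and 217 without anoxia replicate 1, 598 and 445 without anoxia replicate 2, 328 and 166 without heat then anoxia replicate 1, and 185 and 199 without heat then anoxia replicate 2. With replicate as a block they were 784 and 592, and at adjusted p below 0.01 in limma 114 and 112. Without the 2 arrays with a high 25S signal they were 91 and 136, so which was larger depended on the arrays kept. AT1G69760 was not called without control replicate 1, control replicate 2, anoxia replicate 1, anoxia replicate 2 or heat then anoxia replicate 2 (adjusted p of 0.0679, 0.0830, 0.0759, 0.0532 and 0.0859), Hop3 without heat replicate 2 (0.0508) and AT3G07010 without heat replicate 2 (0.0542).

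Transcripts encoded in the mitochondrial genome were examined after their values were seen, because nad1 and nad5, subunits of respiratory complex I, were among the strongest negative interactions (-5.50 and -5.41). Of 16 measured mitochondrial-encoded genes 14 rose in heat with a median of 6.16, 11 rose in anoxia with a median of 2.73 and 15 rose in heat then anoxia with a median of 5.62. Camera gave adjusted p = 1.90e-15, 1.72e-13 and 1.44e-12, with adjusted p = 0.135 in each with an estimated correlation. Of 69 plastid-encoded genes 1 rose in heat, psbA at 2.34, and the medians were 0.10, 0.40 and -0.16. In anoxia 0 were called, and in heat then anoxia 5 rose and 3 fell. Camera gave the plastid list adjusted p = 0.0581, 0.00422 (upward) and 0.398, with adjusted p = 0.869, 0.773 and 0.895 with an estimated correlation. The several probe sets of nad1 gave heat values from 2.34 to 7.77. In controls nad1, at the probe set with the interaction of -5.50, stood at 3.29 and 3.39, and nad5 at 3.75 and 3.31. These signals lie below log2 4, so the size of the folds and interactions of these genes depends on the background model.

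**Figure D3:**
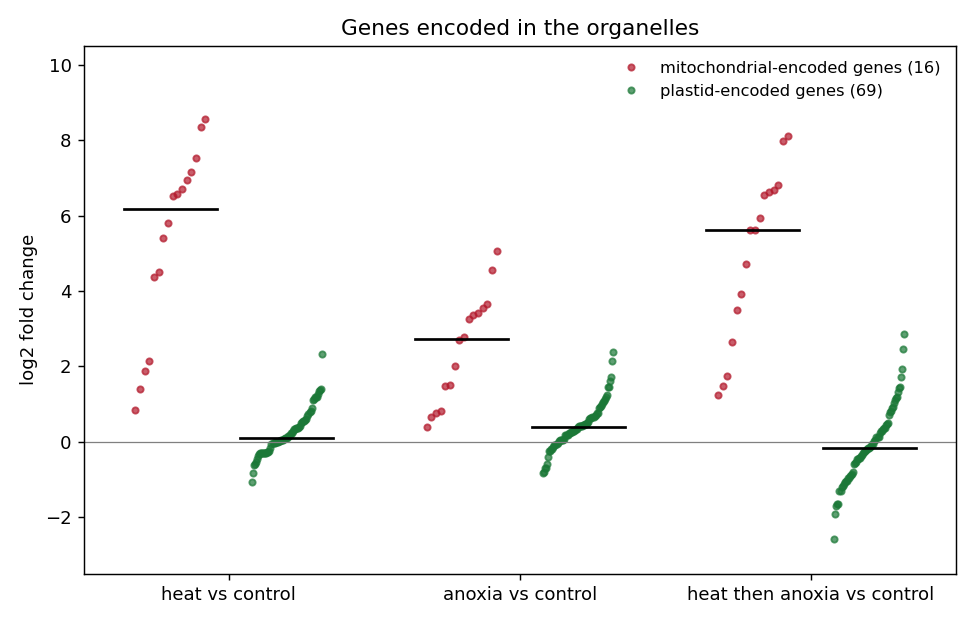
Log2 fold change of each measured gene encoded in the mitochondrial (16) and plastid (69) genome in 3 comparisons with control (dots, ordered by value) with the median (bar). Mitochondrial medians are 6.16, 2.73 and 5.62, and plastid medians 0.10, 0.40 and -0.16.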

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

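The tests of the rise of mitochondrial-encoded transcripts were chosen only after their results were seen. The lists of mitochondrial- and plastid-encoded genes, class III peroxidases and root hair-specific genes were also chosen after values were seen.

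Among probe sets called in the same direction in both single treatments, heat and anoxia mostly combined to less than their sum on the log2 scale. Of the 641 lower in both, 622 had a positive value. The totals that follow cover all probe sets, and 84 of the positive and 119 of the negative calls were of probe sets called in neither single treatment. The interaction was positive for 542 probe sets and negative for 356 (784 and 592 with replicate as a block, 91 and 136 without the 2 arrays with a high 25S signal), and of the 313 probe sets higher in both single treatments 302 had a negative value. Probe sets were chosen on the same arrays that give the interaction, which alone pushes these values towards opposing signs. Additive simulations gave medians of -0.25 to -0.12 for sets higher in both and of 0.15 to 0.24 for sets lower in both. The observed medians were -2.20 and 1.61. The counts of 302 and 622 may thus follow in part from the choice, while medians of this size did not arise in the simulations. Saturation at log2 13 or above is argued against as the whole cause. The 238 of these 313 below log2 13 in heat and in heat then anoxia had a median of -1.98, where additive simulations gave -0.37 to -0.20. A floor below log2 6 is argued against likewise as the whole cause. The 169 probe sets lower in both, at log2 6 or above in heat and in heat then anoxia, had a median of 1.43, where simulations gave 0.25 to 0.43. In the simulations these sets held a median of 299 and 207.5 probe sets. The bounds were set on observed means, so probe sets whose sum lay beyond a bound could enter in the data but seldom in the simulations. The gap therefore does not give the size of the departure, and saturation of single probe sets below log2 13 was not tested. Saturation stays open for the chaperone genes listed below and for AT3G10020 and AT3G03270, which lay above log2 13. A floor stays open for 97 of the 245 positive interactions among probe sets lower in both, which lay below log2 4 in all 3 treated groups. The unstated time from heat to harvest stays open too. A shared pathway that either stress drives near its limit may also apply and was not tested.

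Mitochondrial-encoded transcripts rose in heat by a median of 6.16, with an interaction median of -3.34. The control signals of nad1 (3.29 and 3.39) and nad5 (3.75 and 3.31) lay below log2 4, so the size of their changes depends on the background model. A rise of all organelle RNA is argued against by the plastid-encoded median of 0.10 (SD 0.61), which lies 6.06 below and ran from -0.29 without control replicate 1 to 0.52 without heat replicate 1. The 3' to 5' difference of the GAPDH and actin controls was -0.23 in heat relative to control, so it did not rise. That value cannot decide on RNA degradation, which stays open. The GAPDH probe sets and the actin 3' probe set were near the top of the array's range, where a shift may not show. These controls also do not measure mitochondrial RNA. Longer tails or slower turnover of mitochondrial RNA may be involved, as may transcription from the nuclear copy of mitochondrial sequence, and neither was tested.

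The root hair-specific genes EXPA7, EXPA18 and AT1G30870 had medians of -2.99 in heat and -3.73 in anoxia; all 6 treated arrays lay below log2 4, so their interaction median of 3.10 may be a signal floor only. A single control array with high signal is argued against, since the medians were -2.12 and -2.93 without control replicate 1 and -4.05 and -4.54 without control replicate 2. Less root tissue cannot be told apart from a change within root hairs, because only 1 endodermis gene was measured, AT1G61590. It stood at -1.21 ± 0.74 (SE) in heat and 0.46 ± 0.74 in anoxia, and both values lie above the root hair medians. Its 2 heat arrays were far apart at 5.34 and 7.99, against 8.08 and 7.68 in controls. A single gene has no spread between genes to set these values against, so no conclusion is drawn from it. Less root tissue or a change within root hairs may apply, and a biological effect on root hairs was not tested further.

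The following values were picked out by the test of the interaction. Median interactions were -5.58 for small heat shock proteins, -2.79 for larger chaperones and co-chaperones, 1.00 for class III peroxidases (3 of their 7 positive calls lay below log2 4 in all 3 treated groups) and -0.67 for plastid-encoded genes; none of these lists was called with an estimated correlation (adjusted p = 0.116, 0.271, 0.146 and 0.765). The plastid list had 1 of 69 members called and was not called without control replicate 1 (-0.26, adjusted p = 0.120), heat replicate 2 (-0.36, 0.188) or heat then anoxia replicate 1 (-0.07, 0.439), and its median was -1.35 without heat then anoxia replicate 2. Positive interactions were those of AT3G06070 (6.48), AT1G69760 (5.89), AT3G04010 (5.75), AT1G30870 (4.66, near background in all 6 treated arrays, so a floor stays open), AT3G55840 (4.48), AT1G67340 (4.34), AT1G21050 (4.30) and AT3G07010 (4.14). Negative interactions of chaperone genes were those of AT1G53540 (-8.95), AT1G52560 (-8.60), AT1G71000 (-7.42), AT5G51440 (-7.03), AT1G54050 (-6.38), ATHSP22.0 (-5.58), Hop3 (-4.86), AT5G48570 (-4.30), AT2G20560 (-4.25) and HSA32 (-3.54). Further negative interactions were those of nad1 (-5.50, 1 of its probe sets), nad5 (-5.41), AT3G10020 (-4.50) and AT3G03270 (-2.25).

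Among array controls outside the comparisons, the probe set for 25S ribosomal RNA exceeded both control arrays (6.90 and 73.5) in heat replicate 2 (95.5), anoxia replicate 2 (4675.7) and heat then anoxia replicate 2 (2816.3).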

How the results depend on the processing

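Leaving out the 2 arrays with a high 25S ribosomal RNA signal was chosen only after the data were seen; the other alternatives were planned. No called gene or list had the opposite test direction under any alternative run, but list medians changed sign, for example core hypoxia in heat from -0.41 to 0.03 without control replicate 2, the chaperone medians in heat then anoxia against heat from 0.06 and 0.07 to -0.03 and -0.01 without heat replicate 1, and plastid-encoded genes in anoxia from 0.40 (called) to -0.04 (not called) without control replicate 1, and in heat then anoxia from -0.16 (not called) to 0.45 (called) without heat then anoxia replicate 1. Of 277 results for named genes under 19 settings, 5016 comparisons stayed on their side of the threshold, 139 lost and 45 gained a call. What dim signals do to directions was not tested.

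With no filter, heat then anoxia against heat had 423 higher and 338 lower probe sets, of which 104 and 42 were shared with anoxia against control. With only the groups compared in the fit, anoxia against control had 524 lower, the count lower in both heat and anoxia was 418, and 37 anoxia-lower probe sets were also lower in heat then anoxia against heat. The replicate block gave 592 negative interactions and changed no other count by over 1.5 times. The labels do not say that a number marks a shared batch. Deviations of same-numbered arrays correlated across probe sets at 0.02 to 0.30 in the 6 pairs of groups, and replicate 2 had the higher 25S and lower BioB signal in all 4 groups, so a shared handling by number is not excluded. At adjusted p below 0.01, fewer pass by construction: 1728 lower in heat, 314 higher and 353 lower in anoxia, 1288 lower in heat then anoxia against anoxia, 242 and 101 against heat, 114 and 112 for the interaction, 191 and 270 shared by heat and anoxia, and 571, 70 and 12 for heat-lower, anoxia-higher and anoxia-lower probe sets called again in the comparison with no array in common. Without both high-25S arrays, which leaves fewer samples, the counts were 286 and 413 in anoxia, 1631 lower in heat then anoxia against anoxia, 213 and 228 against heat, 91 and 136 for the interaction, 186 and 324 shared, and 62 and 17 called again. Apart from the stricter threshold, the cause was not tested for any setting. The loss of samples was not told apart from the 25S signal, since no other pair of arrays was left out.

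With an estimated correlation no camera call held. Small heat shock protein medians of 8.13, 5.62, 8.17 and -5.58 (heat, anoxia, heat then anoxia, interaction) had adjusted p = 0.116, and 2.55 (against anoxia) had 0.135. Larger chaperone medians of 7.24, 2.96, 7.25, 4.00 and -2.79 had 0.146, 0.226, 0.171, 0.175 and 0.271. Core hypoxia medians of 1.80, 0.92 and 1.302 (anoxia, heat then anoxia, against heat) had 0.154, 0.407 and 0.232. With fry, which tests a list by itself and not against other probe sets, all 18 results of these lists kept their side of the threshold. In heat fry gave adjusted p = 1.19e-05 for small heat shock proteins and 0.000179 for larger chaperones. For core hypoxia genes in anoxia it gave adjusted p = 0.00534. Of the results for the other lists, 47 kept their side, 10 gained and 3 lost a call.

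With each array left out in turn, counts ran from 358 to 575 higher and 454 to 762 lower in anoxia, 212 to 766 higher and 110 to 805 lower in heat then anoxia against heat, 185 to 598 and 153 to 445 for positive and negative interactions, 355 to 579 lower in both, 88 to 187 anoxia-higher and 21 to 153 anoxia-lower called again. The core hypoxia interaction median ran from -0.83 (called without control replicate 2, adjusted p = 0.000279) to 0.0647 (without control replicate 1). The other counts of probe sets stayed within 1.5 times when 1 array was left out.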

Other observations

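All lists in this part were chosen only after the data were seen; the tests of the root hair genes were written before their results.

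Class III peroxidases, which use hydrogen peroxide to modify cell walls, had more falls than rises. Of 33 measured members 23 fell and 0 rose in heat (median -1.69), 11 fell and 1 rose in anoxia (median -1.07) and 22 fell and 0 rose in heat then anoxia (median -1.92), with camera adjusted p = 8.81e-07, 1.59e-06 and 8.97e-05, and adjusted p = 0.135, 0.135 and 0.168 with an estimated correlation. The list shares AT1G30870 with the root hair-specific genes, whose EXPA7 and EXPA18 also fell. Against anoxia 1 was higher and 9 lower, and against heat 4 and 2.

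Calmodulin-like proteins, which bind calcium, moved both ways. Of 15 measured members 4 rose and 4 fell in heat, 4 and 1 in anoxia, and 6 and 3 in heat then anoxia, with 0 camera calls at adjusted p below 0.05. The heat median was -0.54 and the mean 0.71. CML37 rose by 6.66, 2.37 and 7.45 in these comparisons, AT1G76640 by 2.22, 6.23 and 5.48, and in heat AT1G21550 rose by 8.63 and CML23 by 3.88.

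Among mitochondrial-encoded genes, heat values ran from 0.83 (nad2, not called) to 8.57 (nad6), with ccb203 at 7.54, nad4L at 7.15, cox2 at 6.71 and cox1 at 5.80. In heat then anoxia 12 of 16 were higher than in anoxia (median 2.55) and 0 of 16 were called by limma against heat (3 at an unadjusted p below 0.05, median -0.39); camera called the list lower without heat replicate 1 (adjusted p = 0.0142) and without heat then anoxia replicate 2 (0.0293).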
